A study of Mus musculus with 12 samples.

How the data were processed

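RNA sequencing libraries were made from primary adipocytes of mouse inguinal white fat, 6 from wild-type (WT) and 6 from FI3OE mice. Per the labels, the cells were released by collagenase digestion and flash frozen, RNA was taken with Trizol, and libraries were built with an Illumina TruSeq RNA kit. The strain label reads C57BL/6 and the age 8 weeks in all 12 samples. The labels do not spell out FI3OE, so the name is kept as given. No label says that the samples of a group came from separate animals. The p-values therefore measure the spread between these samples.

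The deposited values are raw counts of reads per gene, whole numbers that were not normalized. Per the submitters' processing notes, bcl2fastq, HISAT2, Picard, featureCounts and edgeR were used with the mm10 build. Their versions, the use of strand and the treatment of reads that match several places are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart, and near-identical family members (Ifit, Oas, Gbp and H2 genes) can share or lose reads. The table held 31854 rows, each with a UCSC known-gene identifier and a symbol, of which 21701 had a count in at least 1 library. In all, 790 symbols stood on more than 1 row. Such rows were tested separately, and the row with the most counts stood for the symbol in gene lists. Every per-sample column matched 1 sample by name.

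Total counts ran from 16544770 to 21463936 in WT and from 16218312 to 20228497 in FI3OE libraries. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 7.24 and 49.4 over genes with at least 10 counts in a pair, so no library was taken for a repeat of another. The correlation of log2 CPM between replicates lay between 0.959 and 0.990.

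Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13723. Libraries were scaled by TMM factors, and genotype was tested with the robust quasi-likelihood F-test (glmQLFit, glmQLFTest) with no other covariate. P-values were adjusted by the Benjamini-Hochberg method over all rows tested, with a threshold of 0.05. Levels are TMM-normalized CPM, given as mean ± SD over 6 libraries. Standard errors of log2 fold changes were derived from the F statistic. The common biological coefficient of variation was 0.190.

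In all, 46 gene lists of pathways, gene families, cell type markers, sex-linked genes and dissociation stress were fixed before the data were examined, as were the test, the rule for naming genes and most alternatives. Of these, 40 had at least 3 tested members and entered limma's camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the 40 lists. Camera with an estimated correlation and fry were run as alternatives. The level of a list in a library is the median of its members' log2 CPM (prior count 2), each centred on its mean over the 12 libraries. Genes were named by rule: a panel of 10 genes, the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 2 and a symbol that is not a clone name (Gm followed by digits, or Rik), and up to 4 members with the smallest p of each list. Other genes, such as Plscr2, Mpc2 and the neighbours of a named gene, were chosen after their values were seen.

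Positions are those of NCBI RefSeq genes on GRCm38.p6, the assembly of mm10, matched by symbol for 12914 of the tested rows, with strand from GENCODE M21. They describe the gene as a whole, not the exons counted.

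The procedure was tested on simulated counts for FI3OE against WT with known changes, 13599 genes passing the filter. It recovered 77.1% of 96 genes changed by 1 on the log2 scale and 96.8% of 95 genes changed by 2, with 3 false calls. A simulation with no change gave 0 calls among 13618 genes. The simulated genes varied independently, with no cell content or other factor shared by the genes of a library. These rates may therefore not hold for the real libraries. Alternatives were DESeq2 1.42.0, limma voom with and without sample weights, other scalings and filters, a surrogate variable (sva 3.50.0), the replicate number as a block, marker levels as covariates and the removal of libraries.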

Results

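Gene expression was measured by RNA sequencing in primary adipocytes isolated from the inguinal white fat of 8-week-old mice, 6 samples from WT and 6 from FI3OE animals. Sequencing depth was alike in both groups, with 16544770 to 21463936 counts per library in WT and 16218312 to 20228497 in FI3OE (n = 6 each). The series title concerns the transcription factor IRF3, the ubiquitin-like protein ISG15 and the thermogenic and metabolic program of adipocytes, so the comparison of the genotypes addressed these genes and pathways. All 12 libraries carried male transcripts: Ddx3y stood between 204.4 and 269.1 CPM and Xist between 0.15 and 0.63 CPM.

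Irf3, which encodes a transcription factor that switches on interferon and interferon-stimulated genes, was read first as a check of the labels. Irf3 (uc009gsm.2, chromosome 7, 44997648 to 45002848, plus strand) rose from 45.9 ± 2.07 CPM in WT to 489.5 ± 99.3 CPM in FI3OE libraries (SD, n = 6), a log2 fold change of 3.41 ± 0.13 (SE; edgeR adjusted p = 7.48e-09). Every FI3OE library, at 323.2 to 585.3 CPM, lay above every WT library, at 44.1 to 49.6 CPM. Counts at this gene do not separate reads of the resident gene from those of any added copy. The genes on either side, Bcl2l12 (log2 fold change -0.22) and Scaf1 (-0.056), did not pass the test.

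Isg15, whose product is conjugated to proteins during the interferon response, was higher in all 6 FI3OE libraries than in any WT library. Isg15 (uc012dri.1, chromosome 4, 156199424 to 156200818, minus strand) rose from 2.89 ± 1.05 to 36.8 ± 13.1 CPM, a log2 fold change of 3.68 ± 0.29 (edgeR adjusted p = 1.81e-05).

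**Figure D1:**
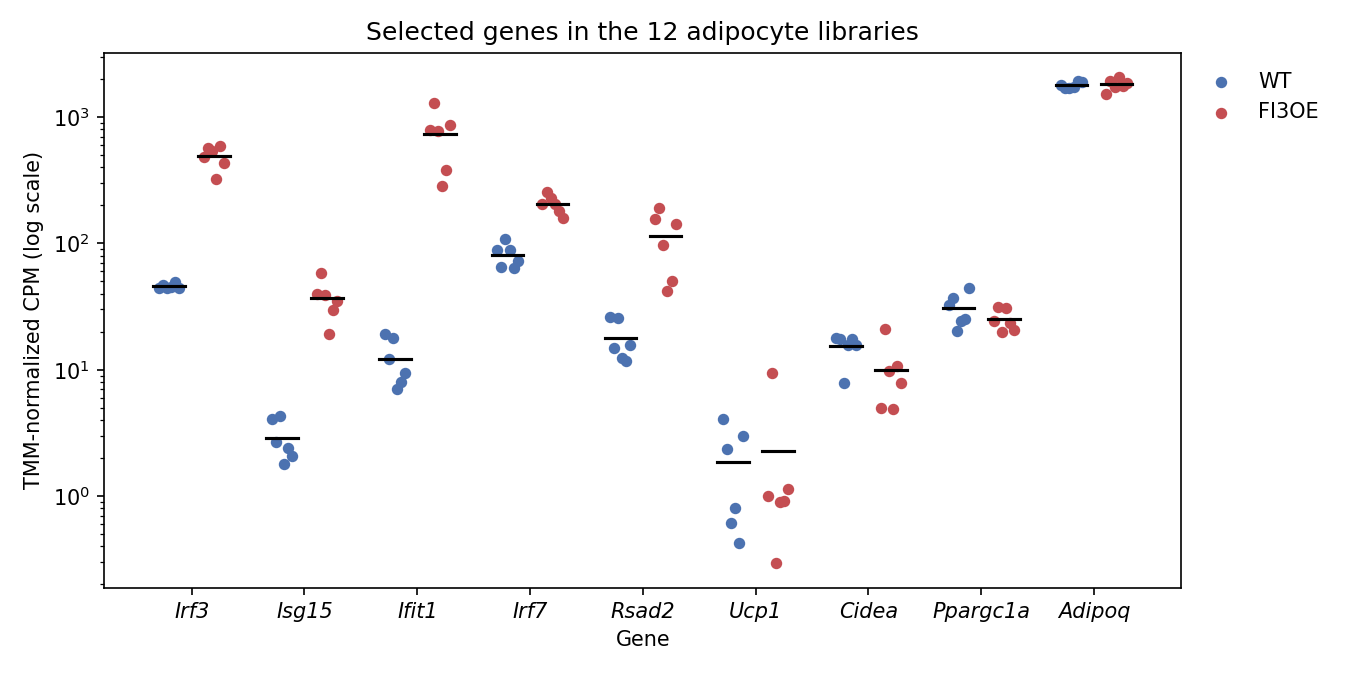
TMM-normalized CPM on a log axis for 9 genes, with 1 point per library (6 WT and 6 FI3OE per gene) and a bar at the mean of each group. Irf3, Isg15, Ifit1, Irf7 and Rsad2 show no overlap between the groups, whereas Ucp1, Cidea, Ppargc1a and Adipoq overlap.

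Across the transcriptome, 218 of 13723 genes changed by edgeR's quasi-likelihood test, 198 of them higher and 20 lower in FI3OE adipocytes. The higher genes rose by a median of 1.94-fold, and 94 rose by at least 1 on the log2 scale. The lower genes had a median fold of 0.641, and 3 fell by at least 1 on that scale. In 151 of the higher and 18 of the lower genes the 2 groups did not overlap. Among all tested genes 1.83% were separated in this way, against 0.216% by chance. The count differed between settings: DESeq2 called 474 genes, and edgeR called 97 with the endothelial marker level of each library as a covariate and 145 without WT 5 and WT 6. The endothelial level itself differed between the genotypes (mean -0.27 in WT and 0.26 in FI3OE), so this covariate takes up part of the genotype difference. A call lost with it does not show that a change came from endothelial cells.

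Irf3 and Isg15 aside, the naming rule picked 8 genes with the largest rises. Ifit1, an inhibitor of foreign RNA translation, rose from 12.2 ± 5.15 to 730.3 ± 363.2 CPM (log2 fold change 5.90 ± 0.44, edgeR adjusted p = 9.82e-06). Oasl1 rose by 4.39 ± 0.45 on the log2 scale, the cytosolic RNA sensor gene Ifih1 by 3.23 ± 0.28 and the zinc finger gene Zfp711, on the X chromosome, by 3.0 ± 0.33. They were followed by Rsad2 at 2.69 ± 0.39, Ddx60 at 2.60 ± 0.13, Rtp4 at 2.58 ± 0.21 and Gbp5 at 2.51 ± 0.35. In each of these 8 genes all 6 FI3OE libraries lay above all WT libraries, and each still passed with the endothelial covariate. Ifih1 reached 951.9 ± 376.2 CPM from 101.3 ± 13.9 CPM. The Rtp4 gene model overlaps that of Masp1, which did not pass the test (-0.15).

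Of the 62 interferon-stimulated genes measured, 32 rose and none fell, while 30 did not pass the test. Adjusted over the list alone, 45 rose and 0 fell. The list had a median log2 fold change of 0.62 (camera adjusted p = 3.69e-53; adjusted p = 0.0368 with an estimated correlation). Besides Ifit1 and Ddx60, the smallest p-values belonged to the ubiquitin ligase gene Herc6, up from 30.9 ± 4.99 to 128.7 ± 18.1 CPM (2.06 ± 0.12), and to the guanylate-binding protein gene Gbp7, up from 72.8 ± 4.65 to 192.0 ± 32.2 CPM (1.40 ± 0.10). Irf9 (0.034), Eif2ak2 (0.023) and Oas3 (-0.084), members chosen after their values were seen, did not pass the test. The type I interferon genes gave too few reads to test, with 0 to 4 reads of Ifnb1 and 0 reads of Ifna4 in each library.

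The machinery that attaches ISG15 to proteins rose in part. Of its 7 measured genes, 3 rose, 0 fell and 4 did not pass the test, and 6 rose when adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 3.81e-12; adjusted p = 0.0292 with an estimated correlation). The 3 were Isg15 itself, Herc6 and Uba7, the activating enzyme, which rose from 40.7 ± 3.88 to 62.2 ± 3.31 CPM (0.61 ± 0.066). The deconjugating protease gene Usp18 had a log2 fold change of 0.68 ± 0.17 and an edgeR adjusted p of 0.0687. All genes of this list except Arih1 also belong to the interferon-stimulated list, so its result is not separate from that of the larger list.

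Among the 8 measured IRF genes, Irf3 and Irf7 rose, 0 fell and 6 did not pass the test, with 3 higher when adjusted over the list alone. Irf7, an amplifier of the interferon response, rose from 81.0 ± 17.1 to 205.7 ± 34.5 CPM (1.34 ± 0.14, edgeR adjusted p = 0.000199). Irf4 (0.97 ± 0.28) and Irf2 (0.48 ± 0.33) did not pass. The list's camera call (median 0.26, adjusted p = 3.93e-05) was lost with an estimated correlation (adjusted p = 0.180), while fry gave an adjusted p of 0.000384. Irf3, the gene raised in FI3OE, is itself a member, so neither test is independent of it. The list was not tested without Irf3. The list's median was 0.64 without WT 3, 0.17 without WT 4 and 0.42 without FI3OE 2. The list for nucleic acid sensing upstream of IRF3 also holds signalling genes such as Tank. Of its 13 measured genes, 1, Ifih1, rose, 0 fell and 12 did not pass, and 4 rose when adjusted over the list alone. Ifih1 and Ddx58 also belong to the interferon-stimulated list. Ddx58 (0.33), Tlr3 (0.40) and Tank (0.38) did not pass over all genes. The median of the sensing list was 0.10 (camera adjusted p = 0.0239, or 0.354 with an estimated correlation), and fry gave an adjusted p of 0.0327. Its camera call was lost without WT 6 (adjusted p = 0.0576). The median was 0.054 without WT 4, 0.062 without WT 5 and 0.053 without FI3OE 1.

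Several genes of antigen presentation on MHC class I rose and none fell. Of 18 measured, 9 rose, 0 fell and 9 did not pass, and 17 rose when adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 1.81e-23; adjusted p = 0.0292 with an estimated correlation). With an estimated correlation, camera's calls held for 3 lists, the interferon-stimulated genes, ISG15 conjugation and MHC class I presentation, and for no other of the 40. The calls of the interferon-stimulated and ISG15 conjugation lists are not independent, since they share all ISG15 conjugation genes except Arih1. The class I genes included the peptide-loading factors Tapbp (0.48 ± 0.068) and Tapbpl (0.54 ± 0.078) and the immunoproteasome subunits Psmb8 (0.66 ± 0.098) and Psmb9 (0.69 ± 0.10), each higher in 6 of 6 FI3OE libraries than in all WT libraries. These named genes still passed with the endothelial covariate. The remaining called genes did not: Tap2 (0.40, from 0.33), Psme1 (0.42, from 0.39), Erap1 (0.39, from 0.41), B2m (0.35, from 0.36) and H2-T23 (0.98, from 1.04), each with a larger standard error. For MHC class II, 0 of 6 genes passed the test, over all genes or adjusted over the list alone. Their median was 0.55, with H2-Eb1 at 0.60 and Cd74 at 0.55 (camera adjusted p = 0.0239; adjusted p = 0.669 with an estimated correlation). Leaving out any 1 of WT 2, WT 4, WT 5, WT 6, FI3OE 1, FI3OE 3 or FI3OE 4 ended that camera call, with an adjusted p of up to 0.0959.

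Of 21 cell death genes, 4 rose, 0 fell and 17 did not pass, with 5 higher when adjusted over the list alone. The 4 were the inflammatory caspase genes Casp1, from 8.40 ± 1.32 to 14.2 ± 0.26 CPM (0.76 ± 0.096), and Casp12 (0.52 ± 0.080), the nucleic acid sensor gene Zbp1 (1.37 ± 0.21) and the necroptosis effector gene Mlkl (0.56 ± 0.12). With the endothelial covariate Casp12 (0.43 ± 0.10) and Mlkl (0.63 ± 0.15) did not pass. The camera call (adjusted p = 0.000187, median 0.19) was lost with an estimated correlation (adjusted p = 0.320), while fry gave an adjusted p of 0.0339. The median was 0.42 without WT 3, 0.12 without WT 5, 0.10 without WT 6 and 0.12 without FI3OE 1. Of 24 chemokine and cytokine genes, Ccl5 and Cxcl10 rose, 0 fell and 22 did not pass, with 3 higher when adjusted over the list alone. Cxcl10 rose from 104.3 ± 30.2 to 479.6 ± 176.0 CPM (2.20 ± 0.31), and Ccl5 rose from 0.195 ± 0.150 to 2.48 ± 1.15 CPM. Cxcl9 (0.56) and Il6 (1.11) did not pass. The Cxcl10 gene model overlaps that of Art3, so its reads are less certain. The median of the list was 0.061 and its camera call (adjusted p = 0.0239; adjusted p = 0.815 with an estimated correlation) was lost without WT 2 (adjusted p = 0.0918), WT 5 (0.281), WT 6 (0.0612) or FI3OE 2 (0.0844). The median depended on single libraries, from -0.061 without FI3OE 3 to 0.54 without WT 3, and it was also negative without WT 2, WT 5 or WT 6. It was 0.036 without WT 4, 0.020 without FI3OE 2, 0.095 without FI3OE 1, 0.10 without FI3OE 5 and 0.14 without FI3OE 6. NF-kB targets (14 genes, median -0.12, camera direction up) and complement genes (16 genes, median 0.046) had 0 genes past the threshold. Adjusted over the list alone, 1 complement gene was higher and 1 lower, and 0 NF-kB targets passed. The median of the NF-kB targets was 0.077 without WT 3, and that of the complement genes -0.0073 without FI3OE 5.

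In the edgeR test fewer genes fell than rose, and by less. Gt(ROSA)26Sor, a noncoding transcript of chromosome 6 (113067428 to 113077244, minus strand), fell from 57.5 ± 4.72 to 26.7 ± 2.61 CPM (log2 fold change -1.11 ± 0.076, edgeR adjusted p = 3.40e-06). Gadd45b, a stress-induced signalling gene, fell from 68.7 ± 20.8 to 32.1 ± 8.72 CPM (-1.10 ± 0.22), and the collagen lysyl hydroxylase gene Plod2 from 23.9 ± 2.92 to 12.7 ± 2.92 CPM (-0.91 ± 0.14). Cxadr (-0.90), Egln3 (-0.71), Ppm1m (-0.58), Tbc1d16 (-0.57), Abhd14b (-0.45), Parp3 (-0.44) and Galc (-0.36) completed the 10 largest. All 6 FI3OE libraries lay below all WT libraries in 9 of these 10 genes, Parp3 being the exception with 5. The 20 lower genes belonged to none of the 46 lists, and 8 of them lay within 20 Mb of chromosome 9, a region that held 141 tested genes. Of the 8, Rpl29 (-0.98) stood on another row as well, at 1.88, which did not pass the test. With the endothelial covariate Gt(ROSA)26Sor (-1.01), Plod2 (-0.95) and Ppm1m (-0.47) still passed, while the other 7 of the 10, from Gadd45b (-0.89) to Galc (-0.35), did not. The count of lower genes was 4 with that covariate, 71 by voom with sample weights and 90 by DESeq2, and it was 11 without WT 1, 13 without WT 2, 13 without FI3OE 3 and 11 without WT 5 and WT 6.

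**Figure D2:**
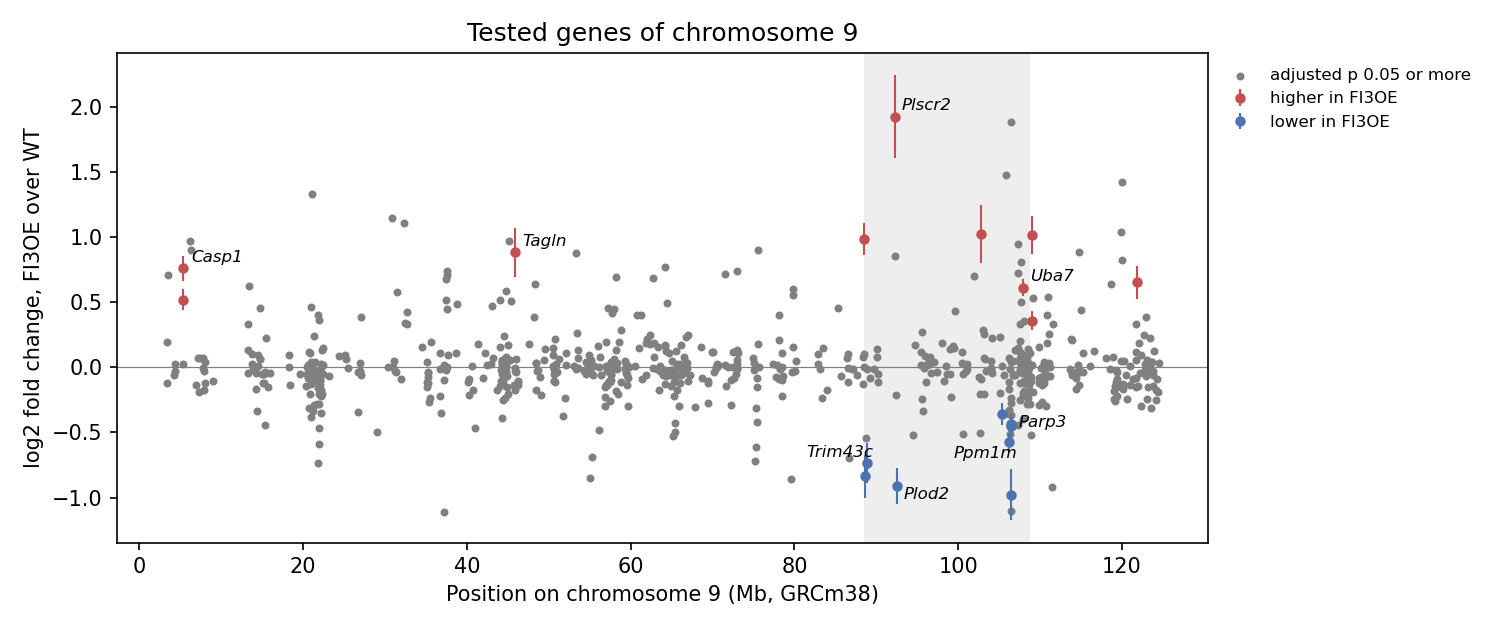
The log2 fold change (FI3OE over WT) of the tested genes of chromosome 9 against their start in Mb. Bars on coloured points are the SE, grey points did not pass the test and the shaded band is the 20 Mb window with 8 lower genes, among them Plod2, Ppm1m and Parp3, and 3 higher genes, among them Plscr2 and Uba7.

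No thermogenic gene passed the test, although most had a negative log2 fold change. Of 28 measured, 0 rose, 0 fell and 28 did not pass, over all genes as well as adjusted over the list alone, and at an unadjusted p under 0.05 there were 6 lower and 1 higher. In the edgeR fit 23 of the 28 had a negative log2 fold change, and the median was -0.23. Camera with the preset correlation called the list lower (adjusted p = 0.000361), but not with an estimated correlation (adjusted p = 0.492), and fry gave an adjusted p of 0.236. With the endothelial marker level as a covariate the median was -0.065 (camera adjusted p = 0.264), and it was -0.36 without FI3OE 2, which had the highest Ucp1 level.

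Ucp1, the uncoupling protein of thermogenic adipocytes, was near the floor at 1.88 ± 1.5 CPM in WT and 2.29 ± 3.53 CPM in FI3OE libraries (log2 fold change 0.29 ± 0.80, edgeR adjusted p = 0.930). FI3OE 2 held 169 reads of it, and the remaining 11 libraries 5 to 69. Without FI3OE 2 the log2 fold change was -1.12. Cidea, a lipid droplet protein typical of brown and beige fat, stood at 15.4 ± 3.80 and 9.88 ± 6.00 CPM (-0.64 ± 0.34, edgeR adjusted p = 0.513), and its log2 fold change without FI3OE 2 was -1.01 (adjusted p = 0.0923). The coactivator gene Ppargc1a (-0.29 ± 0.19, and -0.16 without WT 6) and the beige fat regulator gene Prdm16 (-0.22 ± 0.12) did not pass the test either. The members with the smallest p-values were Plin5 (-0.50), Esrra (-0.31), Ntrk3 (-0.86) and Gpr3 (0.83), with edgeR adjusted p-values from 0.191 to 0.273.

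Energy metabolism differed little. Of 74 nuclear-encoded subunits of oxidative phosphorylation (OXPHOS), 0 passed the test over all genes or adjusted over the list alone, 50 had a negative log2 fold change, and the median was -0.044 (camera adjusted p = 0.156; adjusted p = 0.902 with an estimated correlation). Cox4i1 had the smallest p, at -0.19 ± 0.070. The list was called lower without WT 3 (median -0.085, camera adjusted p = 0.000752) or FI3OE 2 (-0.062, 0.0116), and its median turned positive without WT 5 and WT 6 together (0.0080) or with the endothelial covariate (0.040). Of 20 glycolysis genes, 0 passed by either adjustment, with a median of -0.049 (camera adjusted p = 0.204; adjusted p = 0.815 with an estimated correlation). Pfkfb3 stood at -0.24 ± 0.12 and Pfkm at -0.15 ± 0.077. Without FI3OE 6 the list was called lower (-0.10, camera adjusted p = 0.0441), and with the endothelial covariate the median was 0.049. No mitochondrially encoded symbol was found, so those genes were not analysed here.

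All 22 measured genes of the TCA cycle and pyruvate dehydrogenase had a negative log2 fold change, from -0.20 for Fh1 to -0.0014 for Mpc2, and 0 passed the test over all genes or adjusted over the list alone. The median was -0.055 (camera adjusted p = 0.0239; adjusted p = 0.815 with an estimated correlation), and the call was lost without WT 5 (adjusted p = 0.461), WT 6 (0.190) or FI3OE 1 (0.349). The median was -0.10 without WT 3, -0.018 without WT 5, -0.024 without FI3OE 1 and -0.082 without FI3OE 2. Camera made no call on fatty acid oxidation (median -0.067, 20 genes), catabolism of branched-chain amino acids (-0.026, 18 genes), lipogenesis (-0.029, 20 genes), triglyceride synthesis (0.011, 13 genes, below 0 when scaled by library size only), lipolysis (0.043, 16 genes), cholesterol synthesis (-0.046, 23 genes), insulin signalling (-0.012, 12 genes) or creatine and calcium cycling (0.19, 8 genes). In these 8 lists 0 genes passed over all genes, and adjusted over the list alone 2 genes of amino acid catabolism, Bckdhb and Mccc1, were lower. Fatty acid oxidation was called lower without WT 3 (camera adjusted p = 0.00716), FI3OE 2 (0.00983) or FI3OE 6 (0.0335), and amino acid catabolism without WT 1 (0.0345) or WT 3 (0.00604). With 1 library left out, the medians of several of the 8 lists changed sign. Creatine and calcium cycling did so without WT 2 (-0.028), amino acid catabolism without WT 5 (0.015) or FI3OE 1 (0.0025) and cholesterol synthesis without WT 5 (3.73e-06). Lipogenesis did so without WT 1, WT 5, FI3OE 3, FI3OE 4 or FI3OE 5 (up to 0.097), triglyceride synthesis without WT 2, WT 3, WT 4, FI3OE 2, FI3OE 4 or FI3OE 6 (down to -0.038) and insulin signalling without WT 4, WT 6, FI3OE 3 or FI3OE 4 (up to 0.014). Fatty acid oxidation ran from -0.11 without WT 3 to -0.029 without FI3OE 1, and lipolysis from 0.0065 without FI3OE 3 to 0.10 without FI3OE 1.

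Adipocyte markers were level between the groups. Of 24 measured, 0 passed by either adjustment, with a median of -0.0059 (camera adjusted p = 0.761), which was 0.013 without WT 5 and 0.025 without FI3OE 1. Adipoq, the adiponectin gene, stood at 1789 ± 105.1 and 1813 ± 185.8 CPM (0.019 ± 0.076), Lep, the leptin gene, at 857.7 ± 188.5 and 853.4 ± 131.5 CPM (-0.0073 ± 0.14), and Pparg, the adipocyte master regulator, at 368.7 ± 29.4 and 351.5 ± 23.5 CPM (-0.069 ± 0.066).

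Most markers of blood vessel cells had higher mean values in FI3OE libraries, but few passed the test. All 14 endothelial markers had a positive log2 fold change, with a median of 0.47 (camera adjusted p = 1.21e-08; adjusted p = 0.354 with an estimated correlation). None passed over all genes and 11 were higher when adjusted over the list alone, led by Vwf at 25.5 ± 10.5 and 53.4 ± 21.1 CPM (1.06 ± 0.33) and Emcn (0.60 ± 0.19). Of 9 mural cell markers, 2 rose, 0 fell and 7 did not pass, and 4 were higher when adjusted over the list alone (median 0.60, camera adjusted p = 1.06e-05; adjusted p = 0.126 with an estimated correlation). The potassium channel subunit gene Abcc9 rose from 132.8 ± 14.5 to 202.3 ± 30.1 CPM (0.61 ± 0.10) and the smooth muscle gene Tagln from 6.22 ± 1.77 to 11.5 ± 2.20 CPM (0.88 ± 0.19). With the endothelial covariate neither Abcc9 (0.52 ± 0.14) nor Tagln (0.46 ± 0.17) passed. WT 5 and WT 6 had the lowest endothelial levels, at -0.64 and -0.76 against a WT mean of -0.27 ± 0.39 and an FI3OE mean of 0.26 ± 0.29.

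**Figure D3:**
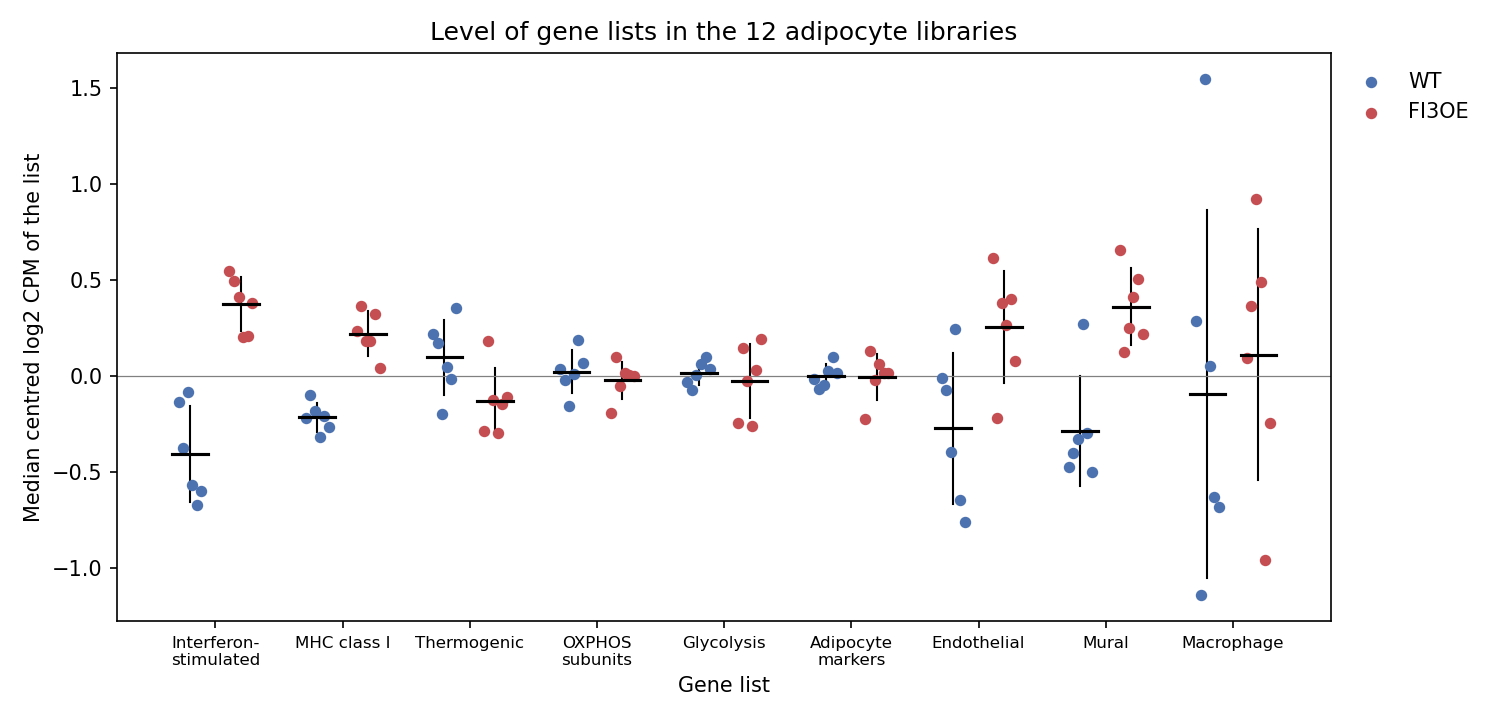
The level of 9 gene lists (median centred log2 CPM of the members) in each of the 6 WT and 6 FI3OE libraries, with the group mean as a horizontal bar and the SD as a vertical line. The groups do not overlap for interferon-stimulated and MHC class I genes, and they overlap for thermogenic, OXPHOS, glycolysis, adipocyte, endothelial, mural and macrophage genes.

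Macrophage markers varied most between libraries of one group, from -1.14 to 1.55 in WT, and 0 of 18 passed by either adjustment (median -0.13 while camera's direction was up, adjusted p = 0.390). They were called higher without WT 3 (0.56, camera adjusted p = 0.00214) or FI3OE 5 (0.017, 0.0144). Leaving out other libraries moved their median the other way, to as low as -0.36, and it was -0.35 without WT 2. Of 15 fibroblast markers 0 passed by either adjustment (median 0.18, camera adjusted p = 0.0485; adjusted p = 0.815 with an estimated correlation), and that call held only when WT 1, WT 3, WT 4 or FI3OE 5 was the library left out. It was lost without WT 2, WT 5, WT 6, FI3OE 1, FI3OE 2, FI3OE 3, FI3OE 4 or FI3OE 6 (adjusted p from 0.0516 to 0.415), and the median was 0.11 without WT 2, 0.30 without WT 3 and 0.049 without WT 6. Of 4 lymphatic endothelial markers 0 passed over all genes and 1 was higher when adjusted over the list alone (median 0.50 with a mean of 0.16, camera adjusted p = 0.0385; adjusted p = 0.360 with an estimated correlation). Leaving out WT 2, WT 5, WT 6, FI3OE 1, FI3OE 4 or FI3OE 6 ended that call, with an adjusted p of up to 0.144, and the median was 0.88 without WT 3 and 0.76 without WT 4. Camera made no call on mast cell (median 0.74, 4 genes, 1 higher when adjusted over the list alone), dendritic cell (0.32, 4 genes), erythroid (0.48, 4 genes), Schwann cell (0.13, 6 genes) or skeletal muscle markers (-0.084, 3 genes). Without 1 library the mast cell list (WT 3, adjusted p = 0.0242; FI3OE 5, 0.0110) and the erythroid list (WT 4, 0.0469) were called higher by camera. With 1 library left out the dendritic cell median ran from 0.18 (FI3OE 4) to 0.56 (WT 3), the erythroid one from 0.25 (FI3OE 4) to 0.71 (WT 4), the Schwann cell one from 0.081 (FI3OE 1) to 0.21 (WT 5) and the muscle one from -0.14 (WT 3) to -0.040 (WT 2). T and NK cell (1 gene), B cell (1 gene), neutrophil (2 genes) and epithelial lists (2 genes) had too few measured members to test.

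Signs of stress differed little. Of 18 immediate early and dissociation stress genes 0 passed by either adjustment, with Hspb1 at -0.47 ± 0.15 and Dnajb1 at -0.57 ± 0.24 (median -0.14, camera adjusted p = 0.0485; adjusted p = 0.815 with an estimated correlation). That call was lost without WT 1, WT 2, WT 4, WT 6, FI3OE 4 or FI3OE 6, with an adjusted p of up to 0.808, and the median was -0.090 without WT 2 and -0.056 without FI3OE 4. Camera made no call on ER stress (median -0.067, 22 genes), NRF2 targets (-0.066, 12 genes), matrix genes (-0.038 with a mean of 0.10, 20 genes), clock genes (-0.0058, 13 genes), cell cycle genes (0.031, 14 genes) or the 4 male sex-linked genes (median 0.0040 with a mean of -0.00019, median below 0 when scaled by library size only). Among these lists only Pcna, the replication clamp gene, passed the test (0.28 ± 0.061, and 0.22 without a call with the endothelial covariate), and adjusted over the list alone Pcna and 1 matrix gene, Eln, were higher. Without FI3OE 5 the ER stress list was called lower (camera adjusted p = 0.0293), and without WT 3 the cell cycle list was called higher (0.0300). The ER stress median ran from -0.098 to -0.027 with 1 library left out. With 1 library left out, the median changed sign for NRF2 targets (WT 5, 0.016), matrix genes (WT 3, 0.0098), clock genes (WT 4, WT 5, WT 6, FI3OE 3 or FI3OE 6, up to 0.043), cell cycle genes (WT 1, WT 2, WT 4, WT 6, FI3OE 1 or FI3OE 3, down to -0.12) and male sex-linked genes (WT 3, WT 4 or FI3OE 4, down to -0.045). Female sex-linked genes had 0 tested members.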

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

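The tests of the vascular markers, and the test of chance placement on chromosome 9, were chosen only after those results were seen. In 6 of 90 group values, 1 library stood far from the other 5 of its group by Dixon's gap test, where chance alone gives about 1 in 20, or 4.5.

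Ucp1 in FI3OE 2 was 3.26 log2 CPM, against -1.31 to 0.33 in the other FI3OE libraries. Cidea in WT 3 was 3.0 log2 CPM, against 3.97 to 4.17 in the other WT libraries. Parp3 stood apart in both groups, lowest in WT 5 at 6.55 log2 CPM (others 6.88 to 7.04) and highest in FI3OE 6 at 6.68 (others 6.35 to 6.44). The level of lymphatic endothelial markers was lowest in FI3OE 5 at -0.66 (others 0.29 to 0.73). The level of mural markers was highest in WT 4 at 0.27 (others -0.50 to -0.29).

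The mean levels of endothelial and mural markers in FI3OE libraries exceeded those in WT by 0.53 (exact permutation p = 0.0303, two-sided; 0.0707 adjusted over 7 lists) and 0.65 (exact permutation p = 0.00866; adjusted 0.0303). Chance could not be excluded for the endothelial list: 5 of 100 splits of the samples gave a median as large as 0.47, the highest other being 0.55. Whether a general carry-over of stromal cells accounts for the endothelial rise could not be told. The endothelial level less the macrophage level differed by 0.32 (exact permutation p = 0.561), and macrophage levels varied too widely (SD 0.96 in WT) to part the 2 cell types. Low vascular content of WT 5 and WT 6 alone also stays open for the endothelial list, as its median was 0.27 without them. For the mural list it is argued against: WT 5 (-0.29) and WT 6 (-0.50) had levels like those of WT 1 (-0.47), WT 2 (-0.40) and WT 3 (-0.32), while WT 4 was at 0.27. A genotype effect on vessels was not tested apart from these explanations.

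Of the 20 lower genes, 8 lay in a 20 Mb window of chromosome 9 (88595325 to 108595325) that held 141 of 12914 positioned genes (1.09%). Chance placement is argued against only for genes that vary independently, since 10000 shuffles gave at most 5 in any such window. The share of 0.0001 is the smallest the shuffles can give. Joint variation of adjacent genes was not kept by the shuffles, and Ppm1m, Rpl29, Abhd14b and Parp3 lie between 106194953 and 106476949. Chance variation shared by such close genes is therefore not excluded. A general fall of the region is argued against too, as all its tested genes had a median log2 fold change of -0.019, above the bound of -0.33 that a general fall would have needed to reach. A graded response to interferon signalling stays open: across the 6 FI3OE libraries the level of the 8 genes against the interferon level gave a Spearman rho of -0.429 (exact permutation p = 0.419) and a Pearson r of -0.21 (exact p = 0.729), or -0.743 without the 2 farthest libraries. A chromosome segment of another strain in the FI3OE samples could also produce such a cluster and was not tested, since that needs the reads. The position of the FI3OE allele is not known here, so its linkage to this region is not known either.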

How the results depend on the processing

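The endothelial and macrophage covariates, the removal of WT 5 and WT 6 or of WT 3 and WT 5, and every alternative for the vascular lists were chosen only after the results were seen. Of 487 values from alternatives over 19 results, 438 kept their direction and side of the threshold, or for counts stayed within 1.5 times. Irf3 (3.35 to 3.51 with 1 library left out), Isg15, Irf7 and the interferon-stimulated list (0.59 to 0.76) passed in every alternative run. The 218 changed genes (198 higher, 20 lower) became 121 (116, 5) at an adjusted p of 0.01 and 97 (94, 3) at a log2 change of at least 1, which are stricter by construction. Voom with sample weights gave 360 (71 lower) and DESeq2 474 (384, 90), the latter with all 218 among them. The endothelial covariate gave 97 (93, 4), of which 93 were among the 218. Removing WT 5 and WT 6 gave 145 (11 lower), of which 132 were among the 218. With 1 library left out there were 162 to 235 (149 to 211 higher, 11 to 26 lower). Ucp1 reversed with the replicate block (-0.15), voom (-0.15), voom with sample weights (-0.91) and without WT 3 and WT 5 (-0.15), and ran from -1.12 to 0.69 with 1 library left out. Lep reversed to 0.0068 (block), 0.050 (surrogate variable), 0.0076 (voom), 0.067 (sample weights), 0.015 (macrophage covariate) and 0.024 (without WT 5 and WT 6), and ran from -0.082 to 0.10. Adipoq ran from -0.022 to 0.066 and Pparg from -0.097 to -0.025. The thermogenic list lost its call with an estimated correlation (-0.23, camera adjusted p = 0.492), fry (-0.23, 0.236) and the endothelial covariate (-0.065, 0.264), and ran from -0.36 to -0.22. OXPHOS reversed with the endothelial covariate (0.040) and without WT 5 and WT 6 (0.0080), and ran from -0.085 to -0.0041. Glycolysis reversed with the endothelial covariate (0.049) and ran from -0.10 to -0.0064. The vascular lists lost their calls with an estimated correlation (endothelial 0.47, camera adjusted p = 0.354, and mural 0.60, 0.126). With fry the endothelial list lost its call (0.47, adjusted p = 0.112) and the mural list kept it (0.60, 0.0117). Beyond the stricter thresholds, the cause was not tested. Replicate numbers did not pair the samples throughout, since only 4 of 12 matched best with their own number. These were the samples numbered 1 (r = 0.33 for log2 CPM less the group mean) and 3 (r = 0.58), so a partial pairing stays possible. With the replicate number as a block 185 genes were called, 155 of them among the 218. Sex as a covariate was not run, all libraries being male. Type I interferon genes were too sparse to compare at this depth.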

Other observations

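The genes and families named here were chosen after their values were seen, and the tests of neighbouring genes took their present form, with induced genes left out of the neighbours, only after the result was seen. The endothelial covariate was also chosen after the data were seen. Guanylate-binding proteins, GTPases that attack intracellular pathogens, rose in 9 of 10 measured Gbp genes and fell in none, with a median log2 fold change of 1.35. All 5 measured immunity-related GTPase genes rose, with a median of 1.33, Iigp1 going from 140.5 ± 43.6 to 360.4 ± 148.6 CPM (n = 6 each). All 6 Ifit genes rose (median 2.41), but only 2 of 8 Oas and Oasl genes did (median 0.39), namely Oasl1 and Oasl2 (1.81 ± 0.27). With the endothelial covariate Oasl2 (1.71 ± 0.37) and Iigp1 (1.59 ± 0.39, from 1.36 ± 0.30) did not pass. Irgm1, Tgtp2, Gbp4, Gbp9, Gbp11, Ifit2 and Ifit1bl1 did not pass with it either. The standard error of each of these genes was larger with the covariate. Their log2 fold changes moved both ways, with Gbp4 at 0.40, from 0.69, and Irgm1 at 1.18, from 1.0. Close relatives in these families can share reads.

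Of the 198 higher genes, 148 were in none of the fixed lists. Ctsc, a lysosomal protease, rose from 135.5 ± 34.6 to 350.6 ± 79.2 CPM, Clu, an extracellular chaperone, from 77.8 ± 19.5 to 290.3 ± 114.4 CPM, and the cannabinoid receptor gene Cnr1 from 142.4 ± 43.8 to 384.0 ± 112.6 CPM. Cd274, which encodes the immune checkpoint ligand PD-L1, rose from 41.0 ± 10.9 to 96.2 ± 41.8 CPM, and Calcrl, a receptor for adrenomedullin, from 24.1 ± 5.27 to 59.7 ± 10.4 CPM. Myo18b stood at 0.0837 ± 0.0782 CPM in WT and 16.8 ± 10.5 CPM in FI3OE libraries. All 6 FI3OE libraries lay above all WT libraries for each of these genes except Cnr1, with 5. Vascular markers also had higher means in FI3OE libraries. With the endothelial marker level as a covariate, Ctsc (1.32 ± 0.26), Calcrl (1.16 ± 0.19) and Myo18b still passed the edgeR test, while Clu (1.76 ± 0.38, from 1.90 ± 0.30), Cnr1 (1.38 ± 0.36, from 1.43 ± 0.26) and Cd274 (1.5 ± 0.30, from 1.23 ± 0.26) did not, each with a larger standard error.

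Eif4a2, which lies beside Adipoq, rose from 354.8 ± 11.9 to 489.2 ± 57.0 CPM, while the log2 fold change of Adipoq was 0.019. With the endothelial covariate that of Eif4a2 was 0.46 ± 0.10, from 0.46 ± 0.075, and did not pass. The neighbours of Gt(ROSA)26Sor, Setd5 (-0.11) and Thumpd3 (-0.15), did not pass the test. The cause of the fall of Gt(ROSA)26Sor was not tested, and counts alone do not tell whether it is a response to the raised Irf3.

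The number of changed genes was larger than in the other splits tried, which argues against chance: 1 of 100 splits, the real one, gave as many as 218, and the highest other gave 4. Not every possible split was among the 100, and 1 of 100 is the smallest share they can give. For the interferon-stimulated list the real split was also the only 1 of 100, but its median of 0.62 was close to the highest other of 0.61. Those splits alone therefore do not exclude chance for this list. The level of the list, compared over all possible splits, gave an exact permutation p of 0.0022 (0.015 adjusted over 7 lists), which argues against chance. For the thermogenic list chance could not be excluded, since 9 of 100 splits gave a median as far from 0 as 0.23, the highest other being 0.42.

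A few genes next to strongly induced genes rose as well. Within 50 kb of 31 genes with a log2 fold change of at least 2, 46 neighbours that were not such genes themselves had a median of 0.063. Of these, 4 rose (8.70%, against 1.22% of the other tested genes), 0 fell and 42 did not pass the test. The 4 were Fap beside Ifih1 (1.49), Agrn beside Isg15 (0.27), Adrbk2 beside Myo18b (1.13) and March5 beside A330032B11Rik (0.31). With the endothelial covariate only Fap (1.48) kept its call, while Agrn (0.22), Adrbk2 (1.36) and March5 (0.33) did not. Chance is argued against for this small shift of the median, since the central 95% of shuffled medians ran from -0.064 to 0.013 and a share of 0.0003 was as high. Transcripts that run past the end of the induced gene stay open as a possible explanation: the mean of 23 downstream neighbours exceeded that of 20 upstream neighbours by 0.10 (permutation p = 0.455, two-sided).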
